A study of Drosophila melanogaster with 2 samples.

How the data were processed

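Both samples are biological replicates, numbered 3 and 4, of transgenic embryos that express Mes4 fused to GFP; per the labels, chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP. For each replicate the authors deposited a relaxed peak list, made per the deposited readme files as input for the IDR procedure from that replicate's alignments and a control that both replicates share. For the series they deposited a relaxed list from the pooled alignments of both replicates with the same control, and an optimal IDR list made from these lists. Each of the 4 kinds of list comes in the genome builds dm6 and dm3, 8 lists in all. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here, and the control itself was not analysed here.

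The files are in the narrowPeak format. The seventh column holds the signal value the authors' caller gave each peak, whose scale is not stated. The ninth column is read as the authors' −log10 of a q-value, which never passes 3.93 and stands at its maximum in all of the optimal IDR peaks, so it could not rank peaks. The tenth is the summit's offset within the peak, another deposited number. All peaks were therefore ranked by signal. Median peak width in the dm6 optimal list was 416 bp (104 to 475), the 3207 peaks covered 1208 kb, and 3110 remained after overlapping peaks were merged. Among the 1000 strongest pooled peaks 53.6% were narrower than the most common width, against 0.0966% of the rest. The optimal list holds, peak for peak, the strongest 3207 of the 30000 pooled peaks in dm6 and the strongest 2923 in dm3. No read counts are in the files, so depth is unknown, and Wilson intervals cover only the counting of peaks or genes.

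Coordinates are 1-based and in dm6, without conversion between builds. The dm6 lists were annotated with Ensembl release 115 (18164 genes on the arms 2L, 2R, 3L, 3R, 4 and X, with 23581 distinct TSSs; transposable elements left out) and the Release 6 RefSeq sequence, whose arm lengths exceed every peak end. A summit was TSS-near within 500 bp of any TSS and distal over 1000 bp from all; other summits were classed in the order 5' UTR, 3' UTR, coding exon, noncoding exon, intron, intergenic. The comparison set for location and arms was the pooled relaxed peaks that no optimal peak overlaps by at least 1 bp.

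A gene was bound if an optimal IDR summit lay within 500 bp of one of its TSSs. The 26 gene lists and 23 motifs (2 of them random controls), the tests and most alternatives were fixed before the data were examined; 25 lists had members in the background and were tested. List members were matched by symbol, by a pattern in the symbol, or by an older name that belongs to 1 gene only, 9 names did not match, and 1 member, don, was left out of the male germ line list because its older name leads to another gene. Named genes follow a rule also fixed then: those at the 20 strongest peaks, the 4 strongest bound members of each list, the 10 strongest distal peaks, the strongest peak of each arm, and Mes4 with Mes-4. Some members that this rule names are not reported here. Genes named for lacking a peak, and those at the peaks around PolE4, were chosen after their values were seen.

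Shares were compared with two-sided Fisher's exact tests, medians with permutation tests of 100000 resamples, and motif matches (both strands) at the summit (100 bp to each side) with exact McNemar tests against windows of the same width 500 bp to each side, keeping the larger p. Adjusted p-values use the Benjamini-Hochberg method within each family of lists, motifs, arms or locations. Replicate overlap was compared with 1000 circular shifts along the arms and 1000 random draws. Promoter motifs were searched within 150 bp of each gene's most 5' TSS. The count of peaks around the tagged gene was ranked among 1000 random protein-coding genes of its arm. Alternatives covered TSS distances of 250 and 1000 bp, summit distances of 100 and 500 bp, overlap rules, the stronger 1603 peaks, each replicate alone (its own 3207 strongest peaks), the dm3 lists, merged peaks, protein-coding TSSs, other gene backgrounds and assignments, motif windows of 50 and 200 bp, and stratification by GC decile.

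Sequences of 8 bp (8-mers) were searched after seeing the data: the 20 most in excess at the summits of even-ranked peaks were tested at the odd-ranked peaks. The steps were also tested on simulated data. With the real lists and 7608 genes, a list raised from 30% to 60% bound was called in 99% of 100 runs, a list lowered to 5% in 100%, and unchanged lists in 0.435%. A motif planted in 4% of 3207 windows was called in all 20 runs. No other motif was, but the BEAF-32 and GATA motifs were left out of that count. The runs reordered the same windows, so they are not independent for motifs that were not planted. All windows lay away from the summits, so the runs do not test how the lower GC content of real summits affects the calls. The permutation test called 6% of 200 comparisons with no difference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.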

Results

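Chromatin from whole Drosophila melanogaster embryos aged 0 to 16 h, of mixed sex, was immunoprecipitated with an antibody against green fluorescent protein (GFP) and sequenced. The embryos came from a transgenic line that expresses Mes4 with GFP fused to its C terminus, a design meant to enrich DNA at sites where the tagged protein binds. A gene with a peak at its start is called bound here. Both samples belong to 1 group, as biological replicates 3 and 4, and no sample from an untagged line or with another antibody was analysed here. The authors' relaxed list for each replicate holds 30000 peaks. Their optimal list, made with an irreproducible discovery rate (IDR) procedure based on agreement between replicates, holds 3207. These are exactly the 3207 strongest peaks of the list pooled from both replicates, so a single peak was not kept for its own agreement. The sequencing depth of each sample is unknown from these files. The design poses 4 questions: how well the replicates agree, where the protein was bound, which genes carry a peak at their start, and which sequences lie under the peaks. With 1 group there is no contrast between conditions, and p-values over peaks or genes describe these lists, since peaks and genes are not replicates.

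The strongest sites lay mostly, though not the first of them, at the starts of genes of varied function, and they came out at nearly the same places in both replicates. The highest peak (2L, 480882 to 481287, dm6) sat in an intron of ush, a cofactor of GATA transcription factors, 1396 bp from the nearest transcription start site (TSS), that of cbt. Next came px (2R, 22514078 to 22514515), CG14100 (3L, 19590438 to 19590798), Ugalt, a sugar-nucleotide transporter (X, 2703698 to 2704075), and Chro, a chromosomal protein of interbands, whose start region is shared with Ssl1 (3L, 22878708 to 22879101). The rest of the 20 strongest peaks lay at CG1888, ph-p (a Polycomb group gene), PNPase, RpL7, Art3 with mRpS10, mRpL41, CenG1A with mRpS23, CG31145, RpS27 and the long noncoding RNAs CR31840 and CR44619, and inside or near CG11050, Lk6, cno and CG13323. Of these 20 peaks, 15 had a summit within 500 bp of a TSS, and none ranked lower than 25 in either replicate. The signal value of each peak is the authors' own and serves here only to rank peaks within a list. It ran from 85.5 to 1678 in the optimal list.

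Replicate 3 and replicate 4 shared 2400 of their 3207 strongest peaks, 74.8% (95% Wilson interval 73.3 to 76.3), counting summits within 200 bp of each other. Shifting the peaks of replicate 4 along each chromosome arm gave 0.946% on average and at most 1.53% in 1000 shifts. Drawing 3207 peaks at random from the whole relaxed list of replicate 4 gave 11.6% on average and at most 13.3% (one-sided permutation p = 0.001 for both, the smallest that 1000 draws can give). Agreement fell with rank. All of replicate 3's 500 strongest peaks were among the 3207 strongest of replicate 4, as were 97.8% of the next 500, 80.5% of the following 1000 and 46.4% of the last 1207. Anywhere in the relaxed list of replicate 4, a match was found for 94.1% of those last 1207 peaks and for 33.2% of the 18000 weakest relaxed peaks of replicate 3. Across the 13952 peaks matched between the relaxed lists, the signal had a Spearman's rho of 0.655, and across 3202 optimal IDR peaks found in both it was 0.711; peaks are not independent replicates, and no p is given. Of the optimal IDR peaks, 2336 (72.8%) were among the 3207 strongest of both replicates and 52 (1.62%) among those of neither. The replicates were compared with a single control shared by both, so part of their agreement can come from that control.

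Gene starts held more of the peaks than any other class of location. Of the 3207 optimal IDR peaks, 1721 (53.7%, Wilson interval 51.9 to 55.4) had a summit within 500 bp of an annotated TSS, against 7746 of the 26045 weaker pooled peaks that no optimal peak overlaps (29.7%, 29.2 to 30.3; odds ratio 2.74, two-sided Fisher's exact p = 4.87e-154). Introns away from a TSS held 1027 optimal peaks (32.0%) and intergenic sequence 378 (11.8%). Coding exons held only 9 (0.281%), against 16.3% of the weaker peaks (odds ratio 0.0145, Fisher's exact adjusted p = 2.72e-212), and 3' UTRs held 23 (0.717% against 2.91%, adjusted p = 1.28e-16). Introns did not differ past the threshold (Fisher's exact adjusted p = 0.116). Since the optimal list is exactly the 3207 strongest peaks of the pooled list, these comparisons set strong against weak entries of that list. The relaxed lists are labelled as peaks and background. The −log10 q-value of the pooled list had a median of only 0.460 and a minimum of 0.110. Many of the weaker peaks may therefore be background rather than weak binding.

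**Figure D1:**
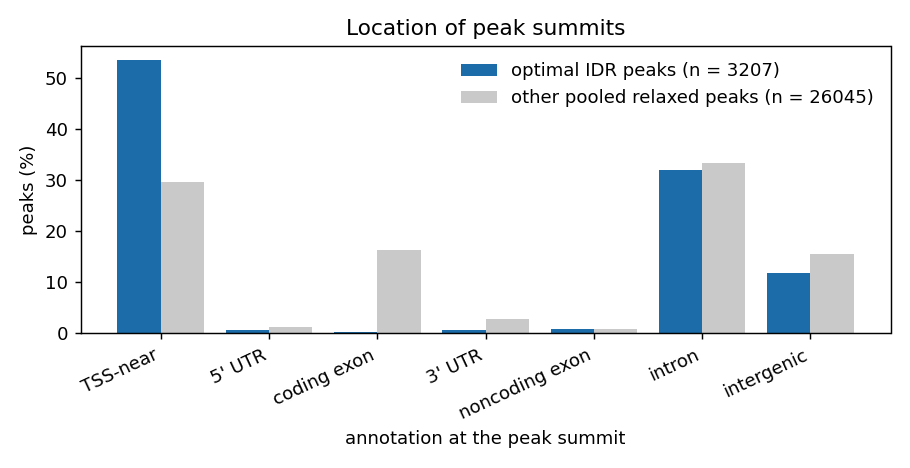
Percent of peaks by the annotation at the summit, for the 3207 optimal IDR peaks (blue) and the 26045 other pooled relaxed peaks (grey). TSS-near means a summit within 500 bp of a TSS; this class holds 53.7% of the optimal and 29.7% of the other peaks, and coding exons hold 0.281% and 16.3%.

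Away from gene starts, 1168 optimal IDR peaks (36.4%) had a summit over 1000 bp from any TSS. The 10 strongest of them were the ush, CG11050 and cno introns above, introns of CG32772, Tlk (a kinase; X, 3742054 to 3742383) and NFAT (X, 13640338 to 13640661), a coding exon of otp (2R, 20884433 to 20884767), and intergenic sites nearest to CG13323 (11893 bp away), CycB (a mitotic cyclin, 3339 bp) and CG31668 (3765 bp). TSS-near peaks had a median signal of 130 (n = 1721) and these distal peaks one of 124 (n = 1168), a difference of 5.57 that did not pass the test (two-sided permutation test with 100000 resamples, p = 0.0695). The share of TSS-near peaks was 58.6% among the 801 strongest peaks and 54.2% among the 801 weakest (n = 801 each; odds ratio 1.19, Fisher's exact p = 0.0867). The strongest peaks of replicate 4 alone passed both tests, and those of replicate 3 alone only the second: the share fell from the strongest to the weakest peaks by 7.62 percentage points in replicate 4 (Fisher's exact p = 0.00259) and by 5.37 points in replicate 3 (p = 0.0344). With a TSS distance of 1000 bp both passed, at p = 0.0373 for signal (permutation test) and 6.62 points (Fisher's exact p = 0.00603). With 250 bp the order of the shares turned round, at -2.12 points (strongest minus weakest, Fisher's exact p = 0.423).

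The 5 large chromosome arms held peaks at similar densities, and chromosome 4 fewer. The X chromosome held 567 optimal IDR peaks (17.7%, Wilson interval 16.4 to 19.0), against 16.7% of the weaker peaks (odds ratio 1.07, Fisher's exact p = 0.177, adjusted p = 0.354 over 6 arms) and 15.7% of protein-coding genes. Peaks per megabase lay between 23.2 on 3L and 25.9 on 2L for the large arms. Chromosome 4, which is small and rich in heterochromatin, held 11 peaks, 8.16 per megabase, and its share of 0.343% against 0.722% of weaker peaks had an adjusted p of 0.0704. The strongest peak of chromosome 4 was intergenic (424725 to 424936), 1238 bp from the long noncoding RNA CR43437 and at rank 195, and that of 3R was in an intron of Lk6 (11760871 to 11761233) at rank 8. The X result depended on the replicate: the 3207 strongest peaks of replicate 4 alone had 18.5% on X (Fisher's exact p = 0.000183), and those of replicate 3 alone 16.8%, below the share of its weaker peaks (odds ratio 0.977, p = 0.673).

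Genes for cytoplasmic ribosomal proteins carried peaks at their starts far more often than other genes. Of 84 such genes in the background, 75 had an optimal IDR summit within 500 bp of a TSS (89.3%, Wilson interval 80.9 to 94.3), against 2026 of 7524 other genes (26.9%; odds ratio 22.6, two-sided Fisher's exact test, adjusted p = 2.65e-31). RpL7 (2L, 10200846 to 10201208, rank 13), RpS27 (3R, 25247331 to 25247684, rank 20), RpL23A (3L, 1668561 to 1668909, rank 22) and RpL14 (3L, 8600793 to 8601149, rank 25) were the strongest, and RpL5, RpL40 and RpS3 were among the 9 without an optimal peak. Among the 801 strongest of all peaks were 55 of the 75, and 70 were among the 3207 strongest peaks of both replicates. The background was the 7608 protein-coding genes with at least a relaxed pooled peak at a TSS, of which 2101 (27.6%) had an optimal one.

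Genes for insulator and architectural proteins, which organise chromatin domains and many of which bind gene starts themselves, were also bound more often: 11 of 14 (78.6%, Wilson interval 52.4 to 92.4; odds ratio 9.66, Fisher's exact adjusted p = 0.00133). Dref, which encodes the factor that binds the DNA replication-related element (DRE), stood at rank 177. It shares that peak with RpL13, whose TSS is nearer to the summit. Chro stood at rank 5, Cp190 at rank 343 and Trl, the GAGA factor, at rank 533. Ibf2, dwg and su(Hw) had no optimal peak. Translation factors followed with 19 of 40 (47.5%, Wilson interval 32.9 to 62.5; odds ratio 2.38, Fisher's exact adjusted p = 0.0454), led by eEF1gamma (rank 81), eIF6 (rank 99), eIF1 (rank 194) and eEF5 (rank 260). The peak of eIF1 is also that of RpL28, whose TSS is nearer to the summit. The call for translation factors was lost with either replicate alone, at 47.2% against 28.9% of other genes without replicate 3 (odds ratio 2.20, Fisher's exact adjusted p = 0.126) and 40.9% against 27.1% without replicate 4 (odds ratio 1.86, adjusted p = 0.298). It was also lost at a TSS distance of 250 bp, with the stronger 1603 peaks, with nearest genes only and without genes that share a start. Over all alternatives its adjusted p ranged from 0.000751 to 0.569. Genes that share a start region cannot be told apart by a peak. Without genes whose TSS lies within 1000 bp of another gene's, the ribosomal protein list was the only one over-represented. The insulator list then had 75% bound, against 19.4% of other genes, but no longer passed (odds ratio 12.5, Fisher's exact adjusted p = 0.281). That p was its highest over all alternatives, the lowest being 0.000206. The odds ratio had not fallen, so the lost call does not show a weaker excess in the fewer genes left.

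Cuticle protein genes stood at the other end, with 0 of 23 bound (upper Wilson bound 14.3%; Fisher's exact adjusted p = 0.00639); Lcp1, Cpr66D and TwdlT were among them. The share stayed at 0% in 4 settings in which the call was lost. These were a TSS distance of 250 bp (Fisher's exact adjusted p = 0.342), the stronger 1603 peaks (adjusted p = 0.164), each peak counted only for its nearest gene (adjusted p = 0.0902) and no genes that share a start (adjusted p = 0.281). With all protein-coding genes as background it was lowest, at 9.20e-08. The list named chemosensory receptors had 2 of 25 bound (8%, Fisher's exact adjusted p = 0.125). These were Ir60e and Obp99b, an odorant-binding protein gene, so the list is not confined to receptors. This list passed at a TSS distance of 1000 bp (Fisher's exact adjusted p = 0.00961), without replicate 4 (0.0366) and with all protein-coding genes as background (6.67e-13). None of the 6 Hox genes in the background was bound (Fisher's exact adjusted p = 0.548). Genes of dorsoventral patterning and mesoderm had 3 of 28 (pnr, if and zfh1, 10.7%, Fisher's exact adjusted p = 0.227) and segmentation genes 3 of 21 (bcd, nkd and wg, 14.3%, adjusted p = 0.548). Neural genes had 2 of 15 (elav and pros, 13.3%), hemocyte genes 1 of 8 (PPO3, 12.5%) and the male germ line list 1 of 9 (Sfp26Ad, 11.1%). None of these lists passed the threshold under the main settings. The male germ line list did with all protein-coding genes as background (Fisher's exact adjusted p = 0.000369). Its bound member, Sfp26Ad, encodes a seminal fluid protein, so the list is not confined to germ line genes.

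Other housekeeping groups, and a few tissue groups, were bound at shares from 23.0% to 50%, none of them past the threshold against the 27.6% of all background genes. Mitochondrial ribosomal proteins had 18 of 67 bound (26.9%, Fisher's exact adjusted p = 1), with mRpS10, mRpL41, mRpS23 and mRpL23 strongest, oxidative phosphorylation 14 of 61 (23.0%; ND-ASHI, ND-MWFE, COX5A and ND-51), proteasome subunits 7 of 30 (23.3%; Rpn5, Rpn3, Rpn6 and Rpn9), spliceosome genes 7 of 25 (28%; Sf3b6, Sf3b1, Prp31 and SmD3) and DNA replication genes 9 of 34 (26.5%; PolE4, dpa, dup and RnrS). Glycolysis had 6 of 12 (50%; Gapdh2, Hex-A, Ldh and Pgk; Fisher's exact adjusted p = 0.372), nucleolus and ribosome biogenesis 9 of 24 (37.5%; Ns2, l(2)k09848 and Surf6 among them), heat shock genes 3 of 8 (37.5%; Hsp83, Hsp26 and Hsp27) and RNA polymerase II and general transcription factors 18 of 51 (35.3%; MED30, MED27, Taf4 and MED4). Chromatin regulators had 15 of 47 (31.9%, with ph-p, Ino80, Sin3A and Kdm2) and cell cycle regulators 12 of 38 (31.6%, with Dp, Rbf2, Cdk1 and tefu). Gut and fat body genes had 2 of 6 (33.3%, fkh and Hnf4) and muscle structural genes 3 of 11 (27.3%, sls, Msp300 and Tm1). The list named zygotic cellularisation genes had 2 of 7 (28.6%). Its bound members, Sxl and rib, are not known as cellularisation genes, so the list is wider than its name. With all protein-coding genes as background, glycolysis, nucleolus and ribosome biogenesis, RNA polymerase II and general transcription factors, chromatin regulators and cell cycle regulators were over-represented (Fisher's exact adjusted p from 0.0133 to 0.0252). Counting each peak only for its nearest gene left 4 of 67 mitochondrial ribosomal protein genes bound (5.97% against 19.9% of others, Fisher's exact adjusted p = 0.0244), fewer than for other genes. The replication-dependent histone genes had no member in the main background, and with all protein-coding genes as background 0 of 111 were bound (Fisher's exact adjusted p = 1.55e-07). None of them had even a relaxed peak at a TSS, which fixed that result. The lists cannot tell a lack of binding at these genes from a lack of reads placed there.

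**Figure D2:**
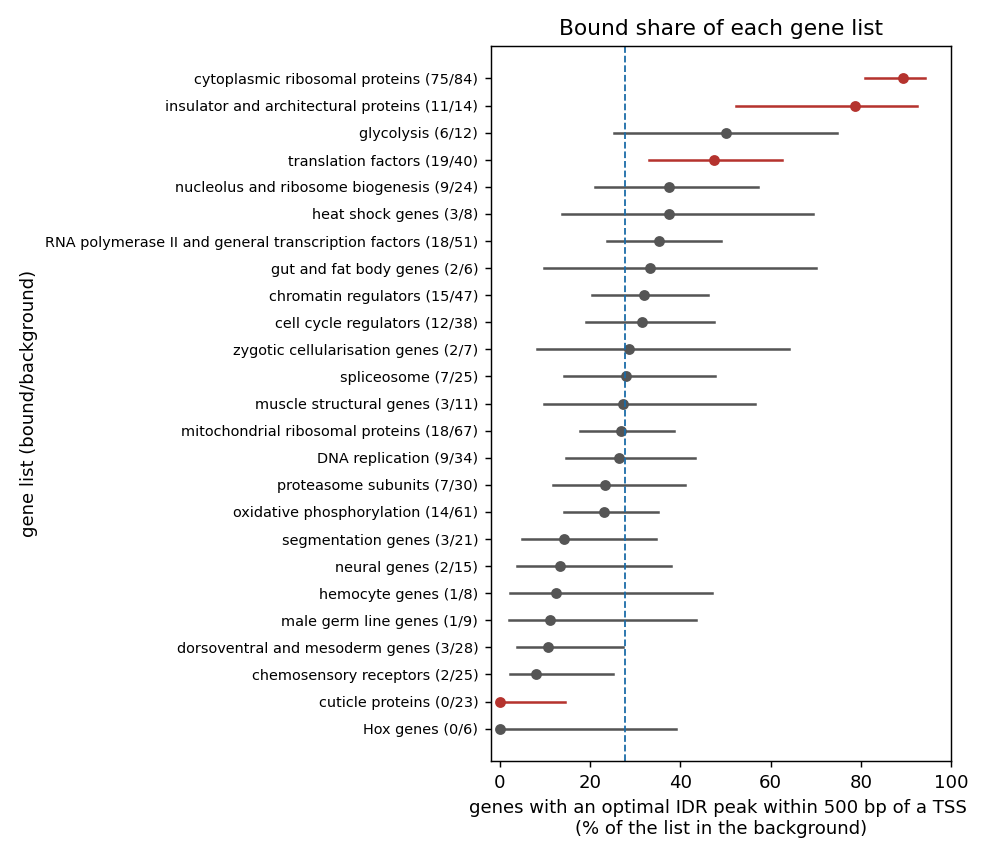
Percent of each list's background genes with an optimal IDR peak within 500 bp of a TSS, with 95% Wilson intervals; the counts beside each name are bound genes over genes in the background. Red marks the 4 lists past an adjusted p of 0.05, from ribosomal proteins at 89.3% to cuticle proteins at 0%, and the dashed line is the 27.6% of all background genes.

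The summits of the peaks held sequences known from housekeeping promoters. The DRE, the palindrome TATCGATA, lay within 100 bp of 146 of the 3207 summits (4.55%), against a mean of 0.515% in the flanking windows (8.85 times; exact McNemar test, adjusted p = 1.43e-25). Motif 7 was found at 6.77% of summits and 1.95% of flanks (exact McNemar adjusted p = 5.70e-18) and Motif 1 at 1.81% and 0.281% (adjusted p = 2.88e-07). Motif 1 did not pass among the stronger 1603 peaks (0.873% and 0.312%, exact McNemar adjusted p = 0.604). The TATA box (28.4% against 20.8%), GATA sites (36.7% against 29.6%) and Mef2 sites (9.82% against 5.92%) were higher at summits as well, while CA repeats (1.81% against 3.48%) and E2F sites (8.04% against 10.3%) were lower. The E2F result did not pass among the stronger peaks (exact McNemar adjusted p = 0.0709), without replicate 4 (0.0799) or with a window of 200 bp (0.761). The CCAAT box, the site of NF-Y, was at 32.8% of summits and 34.8% of flanks (exact McNemar adjusted p = 0.184), and neither random control sequence passed the threshold. The summit windows had a mean GC content of 38.3%, lower than the flanks at 43.3% and 43.0%, and the summit tests were not corrected for this difference. At TSS-near peaks the flanks, centred 500 bp away, often lie farther from the TSS than the summit does. Promoter motifs can therefore be higher at such summits whatever protein is bound.

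The DRE and Motif 1 were more frequent at TSS-near than at distal summits. At TSS-near peaks the DRE was present at 8.19% of summits and 0.581% of flanks, and at distal peaks at 0.257% and 0.300% (exact McNemar adjusted p = 1 at distal peaks); the difference between these classes was not itself tested. Motif 1 was at 3.31% against 0.378% near a TSS and at 0.0856% of both summits and flanks at distal peaks. No motif of the 23 passed the threshold at distal peaks, where GATA sites (40.6% against 32.6%) and the TATA box (27.7% against 22.2%) came closest (exact McNemar adjusted p = 0.0614 for both).

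**Figure D3:**
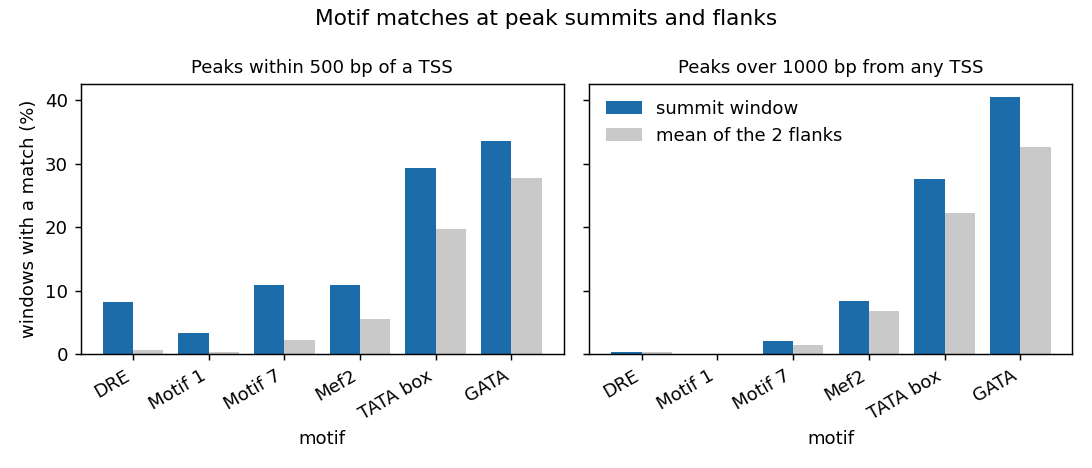
Percent of windows of 201 bp with a match to each of the 6 motifs that were more frequent at summits, at the summit (blue) and as the mean of both flanks (grey), for TSS-near peaks (left) and distal peaks (right). The DRE reaches 8.19% at TSS-near and 0.257% at distal summits.

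Set against other promoters, bound gene starts differed in few motifs. Within 150 bp of the TSS, Motif 7 was present at 16.2% of the 2101 bound genes and 11.7% of the 5507 others (odds ratio 1.45, Fisher's exact adjusted p = 5.09e-06), the TCT initiator of ribosomal protein genes at 27.0% and 23.3% (odds ratio 1.22, adjusted p = 0.00626) and the E-box CACGTG at 6.00% and 4.34% (odds ratio 1.41, adjusted p = 0.0186). The E-box did not pass without replicate 4 (Fisher's exact adjusted p = 0.452). The standard initiator was less frequent, at 27.3% and 33.6% (odds ratio 0.742, Fisher's exact adjusted p = 2.46e-06). The DRE did not differ, at 13.1% and 12.7% (Fisher's exact adjusted p = 0.781), nor did Motif 1 or the CCAAT box pass the threshold. Both random control sequences leaned toward bound genes (0.762% against 0.345% and 0.524% against 0.182%, Fisher's exact adjusted p = 0.0924 for both), and at least 1 of them passed under 4 of the 6 alternatives, so modest odds ratios in this test carry little weight. Leaving out the ribosomal protein genes brought the TCT initiator to an odds ratio of 1.09 (Fisher's exact unadjusted p = 0.142).

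PolE4, a subunit of DNA polymerase epsilon (FBgn0034726, 2R, 22411789 to 22412582), had an optimal IDR summit within 500 bp of its TSS, but a neighbour's TSS lay nearer. The RefSeq gene table gives Mes4 as an older name of PolE4, so it is taken here as the tagged gene, though the label leaves this uncertain. The TSS of PolE4 lay 183 bp from that summit (peak 22411398 to 22411813, rank 795). The start of qkr58E-3 shares the region, and its TSS was nearer, 61 bp from the summit. This peak cannot be assigned to PolE4 rather than to qkr58E-3. Within 20 kb of PolE4 lay 7 optimal peaks, against a median of 1 for 1000 random genes of 2R (percentile 99.55), 3 of them intronic, inside babos. The count of optimal peaks was at percentile 93.4 within 50 kb. In the relaxed lists of replicates 3 and 4, of 30000 peaks each, the counts were at percentiles 95.75 and 96.3 within 20 kb. Within 50 kb they were at 66.9 and 66.2. The pooled relaxed list was at percentile 86.9 within 20 kb and 59.7 within 50 kb. The similarly named Mes-4, now NSD (FBgn0039559, 3R, 27932982 to 27937853), a histone methyltransferase, had no optimal peak at its TSS, the nearest lying 15076 bp away, and 1 within 20 kb (percentile 43.25).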

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

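Matching replicate 4 to replicate 3 and leaving out the weakest 10% of peaks were chosen after seeing the data. The excess of TSS-near peaks passed under all 6 alternatives (44.6% to 63.6%), and the ribosomal protein list under all 9. The overlap between replicates was 66.3% to 79.7% over 8, without a p for these, and the motif count at summits 5 to 9, against 6. Over-represented lists, 3 in the main count, were 8 with all protein-coding genes as background and 1 without genes that share a start; leaving out a replicate gave 2 with either. Under-represented lists, 1 in the main count, were 4 with all protein-coding genes as background, 2 at a TSS distance of 1000 bp, and 0 at 250 bp, with the stronger peaks or without genes that share a start; each replicate alone gave 1 to 2. The larger background holds genes with no peak at all, and leaving out shared starts removes 5985 genes; for the others the cause was not tested. Signal rho between replicates was 0.695 at 100 bp, 0.624 at 500 bp and 0.711 over optimal peaks. At a TSS distance of 1000 bp, TSS-near peaks were stronger than distal ones by 6.01 (permutation p = 0.0373) and the TSS-near share of the strongest 801 peaks exceeded that of the weakest 801 by 6.62 points (Fisher's exact p = 0.00603); at 250 bp that difference was -2.12 points. Without a replicate, the signal difference was 0.781 to 3.23, on each list's own scale and so not comparable in size (permutation p = 0.00607 without replicate 3), the difference in TSS-near share 5.37 to 7.62 points, the X share 16.8% to 18.5% and the percentile at PolE4, counted for each replicate in its whole relaxed list, 95.75 to 96.3; among optimal peaks it was 93.4 within 50 kb. Bound-TSS motifs, 3 in the main count, were 5 at 1000 bp (1 a random control) and 6 under GC stratification (2 of them random controls), the main 3 included, and 2 to 4 without a replicate (1 of the 4 a random control). The cause of these was not tested. Depth could not be examined, as the lists hold no counts.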

Other observations

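The 8-mers, the look at ribosomal protein peaks and the tests of housekeeping function (both of them), of chance, of the distance from a TSS and of extra locus copies were chosen only after the result was seen. Peaks at ribosomal protein genes differed in place from those at other bound genes. Their summits lay a median of 24 bp from the TSS, against 130 bp for 2026 other bound genes (permutation test, p = 1e-05, the smallest that 100000 resamples give), and 57 of 75 (76%) lay within 50 bp, against 19.1%. The other bound genes include more whose summit is nearer to a neighbour's TSS. With only the nearest gene counted, the bound share fell from 26.9% to 19.0% for other genes and from 89.3% to 88.1% for ribosomal protein genes. How much of the difference in place comes from this was not tested. Among noncoding genes and pseudogenes with a relaxed peak at the TSS, an optimal one was present at 6 of 16 snRNA genes (37.5%), 18 of 88 snoRNA genes (20.5%), 5 of 27 pseudogenes (18.5%), 154 of 974 other noncoding RNA genes (15.8%) and 11 of 122 tRNA genes (9.02%), against 27.6% of protein-coding genes.

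Several technical explanations for the ribosomal protein peaks are argued against. If peaks of neighbouring genes were the source, counting only the nearest gene would remove the excess, but 88.1% of the list was still bound, against 19.0% of other genes. Base composition left the odds ratio at 22.3 (95% interval 11.1 to 44.8) when genes were stratified by GC content. Housekeeping function alone is argued against too: all 9 other housekeeping lists together were bound at 31.1% (107 of 344, Wilson interval 26.4 to 36.2), and 3 of them, mitochondrial ribosomal, proteasome and oxidative phosphorylation genes, picked when their shares were known, at 24.7%. What may still account for the pattern is a property not measured here, such as very high transcription, which can enrich DNA with many antibodies, or the shared control; a specific role of the tagged protein at these genes is a hypothesis that an untagged line would test.

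A sequence other than the DRE may mark part of the sites, distal ones included. Of the 20 8-mers picked at even-ranked peaks, 20 passed an adjusted p of 0.05 at odd-ranked peaks, which argues against chance among the 8-mers searched; with the peaks exchanged 20 passed as well, 11 of them the same 8-mers. Their median excess over the flanks was 4.33 times, above the 95th percentile of 2.46 for 184 rearrangements of the same letters, which argues against base composition for these 20, but not for TTTAAAAA, ATTTAAAA and AAAATAAT of the exchanged pick, whose excess was 1.63 to 2.13 times. The 6 that hold ATCGA, such as TATCGATA, may be core promoter elements that come with a TSS: they were at 1.55% of 581 distal summits against 2.24% and 2.07% of the flanks (exact McNemar p = 0.664) but 14.04% of TSS-near ones. The 9 that hold CACTG or its complement, such as CACTGAGA, CACAGTGG and CAACACTG, do not follow the TSS: they were at 24.6% of distal summits (flanks 6.88% and 4.65%, exact McNemar p = 4.71e-16) and 16.3% of TSS-near ones, and a sequence-specific factor at such sites is a candidate explanation that was not tested.

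The cluster of peaks around PolE4, if that is the tagged gene, remains open, and no biological explanation was tested for it. All 7 optimal peaks within 20 kb lie upstream of its TSS or at it, the strongest of them (rank 189) 14.2 kb upstream, inside babos. Gene density is argued against as the whole cause, since the count was at percentile 99.1 among genes of the arm with a like number of TSSs. Extra copies of the locus in the tagged line could raise weak peaks there too. The pooled relaxed list was at percentile 86.9 within 20 kb, 95 within 10 kb and 59.7 within 50 kb. The lists of replicates 3 and 4 were at 95.75 and 96.3 within 20 kb, 98 and 97.35 within 10 kb, and 66.9 and 66.2 within 50 kb. All of these lists also hold the peaks of the cluster itself, so their counts cannot tell extra copies from other causes. How much DNA was inserted is not given in the sources used here.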
